A study of Mus musculus with 6 samples.

How the data were processed

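RNA was measured in 6 samples of mouse bone marrow stromal cells, 3 WT and 3 HRP2-KO, grouped by the genotype in the sample labels and named by the numbers in the sample titles. Per the labels' protocols, RNA was taken up in Trizol and libraries were made with the sequencing provider's standard protocol. The submitters' processing notes name BWA, without a version, and the mouse genome build GRCm38.p6. The program that assigned reads to genes, the annotation release and any use of strand are not given in the sources used here, so overlapping and antisense genes, close paralogs and genes with pseudogene copies are uncertain. Alignment and assignment by the authors decide how such reads are split, which can raise 1 copy of a gene at the cost of another.

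The authors deposited 1 table with 18853 genes. It holds estimated counts per gene, which the authors deposited without normalization and not all of which are whole numbers. The deposited TPM values are scaled by the authors to transcript length and to 1 common total per library, and the deposited FPKM values to length and library size, per the file headers. The FPKM columns sum to between 458878 and 486105 in 5 libraries and to 623178 in HRP2-KO replicate 44. The table also holds 24 average columns and 6 normalized read count columns, which were not used here. Of the 3 deposited WT average columns of the counts, the 1 that was checked differed by more than 1% from the mean of the 3 WT libraries in 12298 of 13839 genes with a mean count above 10. The 13 mitochondrially encoded genes of the fixed list were not among the genes analysed here.

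Estimated counts were rounded to whole numbers. Library totals were 20184500 to 20680800 counts, which allows a level of up to 0.139 to 0.160 CPM for a gene with no count (3 counts, counting error only). Genes with too few counts were removed with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 13696. Normalization used TMM factors, which ranged from 0.906 in HRP2-KO replicate 7 to 1.07 in WT replicate 11. The comparison used edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood F-test (glmQLFit, glmQLFTest) on genotype alone, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM values are normalised with the TMM factors, and means are given with SDs over 3 libraries. Folds are those fitted by the model.

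A total of 26 gene lists with 512 entries was fixed before the data were examined, and 485 entries were found in the table. The 21 lists with at least 5 tested genes, the sex-linked list left out, were tested with limma 3.58.1's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and adjusted over the lists. No list was called with an estimated correlation. Adjusted p-values over a list alone use the edgeR p-values of its tested members. The genes named are Hdgfl2, up to 12 genes in each direction past the threshold with groups that do not overlap and a mean of at least 5 CPM in the higher group, and the 4 members with the smallest p of each tested list, except 1 member that is not reported here. The closing section also names genes that were chosen after their values were seen. Ddx3y, Kdm5d, Eif2s3y and Uty come from the sex-linked list.

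Gene positions come from the RefSeq annotation of GRCm38.p6, the build in the submitters' notes, matched by Entrez ID for 18796 of the 18853 genes (99.7%). Transcript length was taken from the ratio of the deposited counts to the deposited FPKM, and genes were split into 5 groups by length. Libraries were compared in pairs by a chi-square of their counts and by the correlation of log2 CPM.

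The edgeR step was tested on simulated counts with the dispersion of these libraries, over 13564 genes with 50 changed at each fold. It recovered 4% of genes changed 2-fold, 52% of those changed 4-fold, 92% of those changed 8-fold and 100% of those changed 16-fold, with 5 false calls. The camera step, tested on 13696 genes, called 20 of 20 lists raised 1.5-fold and 0 of 100 unchanged lists. Simulated genes were drawn independently, so this test does not cover lists whose members move together. In these libraries the estimated correlation within a list ranged from -0.0125 (histone acetylation and crotonylation) to 0.966 (macrophage), against the preset 0.01.

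Alternatives were RLE and upper-quartile factors, no filter, a filter of 1 CPM in 3 samples, DESeq2 1.42.0, limma voom, limma with trend on log2(TPM + 1) and log2(TPM + 0.1) for genes with a TPM of at least 1 in 3 samples, glmTreat against a fold of 1.5, a minimum fold of 2, camera with estimated correlations, fry, and each replicate left out in turn. A sex covariate from Y-linked expression, a macrophage-level covariate and robust dispersion were added after seeing the data. Figures were drawn with matplotlib 3.10.9.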

Results

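Bone marrow stromal cells (BMSCs), the adherent marrow cells that can form bone, fat and cartilage, were grown in αMEM with 10% serum and profiled by RNA sequencing. The cells carried either an intact or a knocked-out gene for HRP2, also called HDGFR2 and listed in the table as Hdgfl2, a PWWP-domain chromatin protein of the hepatoma-derived growth factor family. There were 3 wild-type (WT) samples, numbered 10, 11 and 12, and 3 HRP2-KO samples, numbered 6, 7 and 44. The series title places the work in osteogenic differentiation and in histone crotonylation and acetylation, while the labels used here do not say that these cultures were induced to differentiate. Each library held between 20184500 and 20680800 estimated counts, and 15863 to 16895 of the 18853 listed genes had a count in a given library. A gene with no count in a library allows a level of up to 0.139 to 0.160 CPM (counts scaled to the library total), a limit of 3 counts that covers counting error only. The labels do not say whether the samples came from separate animals or cultures, so the p-values measure the spread between these samples. The labels also name no batch that holds both genotypes. An effect of batch therefore cannot be told apart from genotype in any contrast below. No pair of libraries within a group agreed within counting noise, and the smallest chi-square per degree of freedom was 41.7, between WT replicates 11 and 12.

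Hdgfl2, the targeted gene (Entrez 15193, GRCm38.p6 chromosome 17, 56079599 to 56100605), was lower in each HRP2-KO library than in each WT library. It stood at 51.4, 56.2 and 58.2 CPM in WT replicates 10, 11 and 12, and at 6.59, 5.56 and 11.8 CPM in HRP2-KO replicates 6, 7 and 44. The group means were 55.3 ± 3.52 and 7.98 ± 3.35 CPM (SD, n = 3 each), a ratio of 6.92 with a log2 fold change of -2.79 and a standard error of 0.32. Over all 13696 tested genes this did not pass the threshold in edgeR's quasi-likelihood test (adjusted p = 0.0711), and adjusted over the list alone it did (adjusted p = 0.00168, list of the HDGF family and H3K36 methylation). DESeq2 gave an adjusted p of 2.9e-10, and edgeR without HRP2-KO replicate 7 gave 0.0152. The part of the gene removed in the knockout is not given in the sources used here, so counts from retained exons cannot be separated from intact transcripts.

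Igf2, which encodes an imprinted growth factor of the insulin family (Entrez 16002, chromosome 7, 142650768 to 142666816), was the 1 gene that passed the threshold over all tested genes. It fell from 151 ± 24 CPM in WT to 3.66 ± 0.649 CPM in HRP2-KO (SD, n = 3 each), 41.2-fold lower, with a log2 fold change of -5.36, a standard error of 0.25 and an adjusted p of 0.00477. No gene rose past the threshold. At an unadjusted p below 0.05 there were 2984 genes, 1738 higher and 1246 lower in HRP2-KO, which is 21.8% of those tested. In 31.0% of genes the 3 HRP2-KO values all lay above or all lay below the WT values, with 2325 genes higher and 1919 lower. Chance gives 10% on average over all groupings of these libraries. Genes move together, so a single grouping can lie far from that average, and the share was not computed for the other groupings. DESeq2 called 1553 genes (840 higher, 713 lower) and limma voom 37, Igf2 among both. Without HRP2-KO replicate 7 edgeR called 3370 genes, 1694 higher and 1676 lower. Without HRP2-KO replicate 44 it called 0, with Igf2 at an adjusted p of 0.0780.

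**Figure D1:**
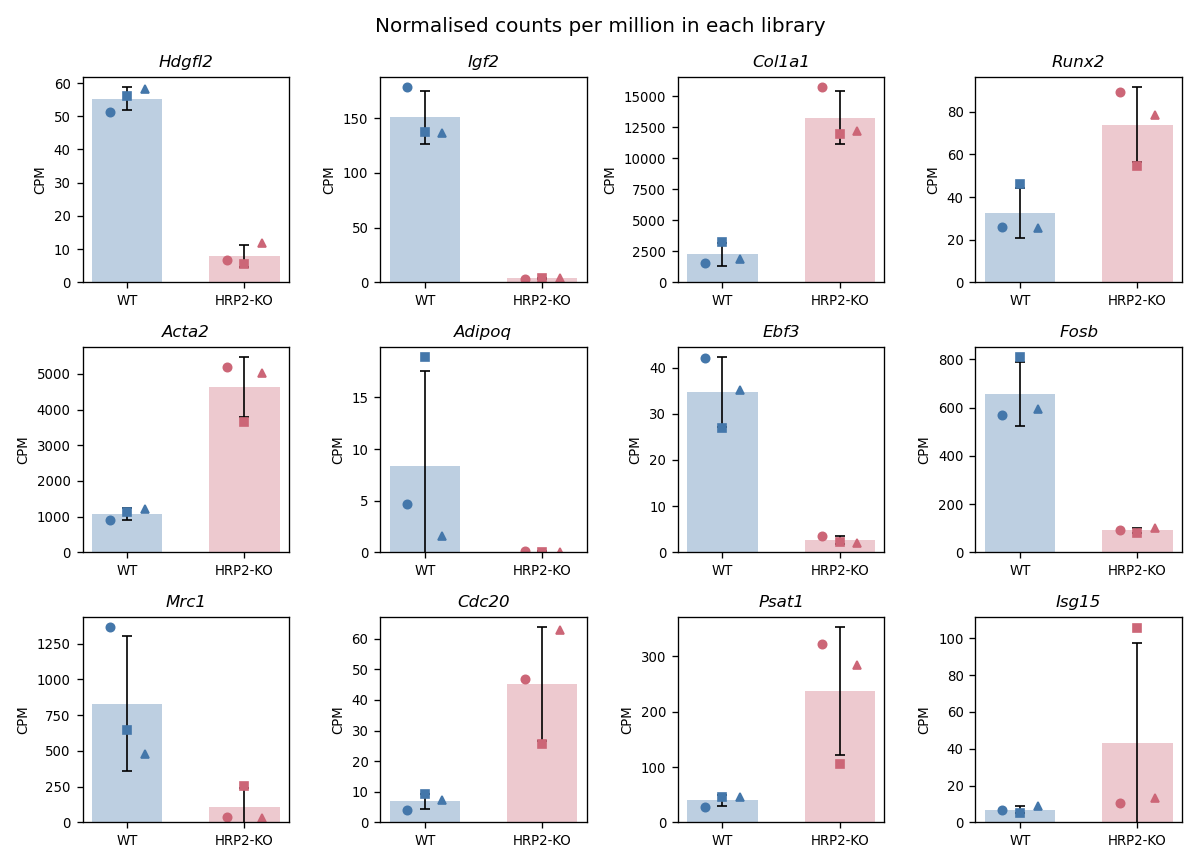
Normalised CPM (vertical axes, linear from 0) of 12 genes in the 3 WT and 3 HRP2-KO libraries. Points are libraries, with a circle, square and triangle for replicates 10, 11 and 12 of WT and 6, 7 and 44 of HRP2-KO, bars are group means and error bars are SDs. Igf2 stands at 137 to 179 CPM in WT and at 2.93 to 4.17 CPM in HRP2-KO, while Isg15 reaches 106 CPM in HRP2-KO replicate 7 and at most 13.2 CPM in the other libraries.

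HRP2-KO replicate 7 differed from the other HRP2-KO libraries more than those differed from each other. Correlations of log2 CPM across genes, which are not independent replicates, were 0.943 to 0.974 between WT libraries, 0.957 between HRP2-KO replicates 6 and 44, and 0.884 and 0.861 between replicate 7 and each of those. With WT replicates 10, 11 and 12, HRP2-KO replicate 7 correlated at 0.912, 0.934 and 0.924. It was thus closer to each WT library than to either other HRP2-KO library. Macrophage genes had a mean log2 CPM of 9.56, 8.15 and 8.09 in WT replicates 10, 11 and 12. In HRP2-KO they had 5.03 in replicate 6, 8.82 in replicate 7 and 6.04 in replicate 44. Interferon-response genes averaged 4.21 to 4.35 in WT, 3.16 and 3.46 in HRP2-KO replicates 6 and 44, and 6.59 in HRP2-KO replicate 7. The first principal component held 59.6% of the variance and placed HRP2-KO replicate 7 at -28.2, beside the WT libraries at -72.4 to -39.6, while replicates 6 and 44 lay at 81.9 and 102. The biological coefficient of variation was 0.432 with all 6 libraries and 0.319 without HRP2-KO replicate 7. The Y-linked gene Ddx3y was at 107 and 58.2 CPM in WT replicates 11 and 12 and at 32.0 CPM in HRP2-KO replicate 44, and had at most 1 count in each of the other libraries. Kdm5d and Eif2s3y, also Y-linked, had 378 to 1572 counts in the same 3 libraries and at most 7 in the others. The values of these 3 genes argue against 1 animal as the source of all libraries of either group. Y-linked Uty, which has a close X-linked paralog, had counts in every library, with 145, 89 and 104 in WT replicate 10 and HRP2-KO replicates 6 and 7 and 274 to 690 in the rest. In HRP2-KO replicate 44 the shortest-transcript group of 2740 genes lay 0.53 above and the longest-transcript group of 2739 genes 0.50 below the average library on the log2 scale.

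**Figure D2:**
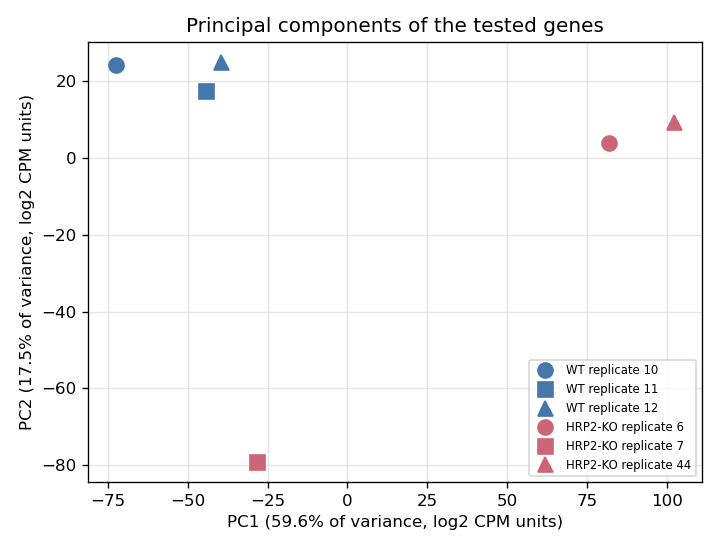
Scores of the 6 libraries on the first and second principal components of log2 CPM over the tested genes (axes in log2 CPM units, 59.6% and 17.5% of the variance). Blue points are WT and red points HRP2-KO, and HRP2-KO replicate 7 lies at -79.2 on the second component while the other libraries lie at 3.80 to 24.8.

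Genes of bone matrix and of the osteoblast lineage were mostly higher in HRP2-KO. Col1a1, which encodes the main collagen chain of bone, was at 13274 ± 2133 CPM against 2242 ± 915 CPM in WT (SD, n = 3 each), 5.92-fold higher. Runx2, the transcription factor that specifies osteoblasts, was at 73.9 ± 17.7 against 32.5 ± 11.7 CPM, and Msx2 at 16.2 ± 1.38 against 7.07 ± 2.60 CPM. Of the 22 tested osteoblast genes 16 were higher, with a median log2 fold change of 0.65. The list mean was 5.18, 5.29 and 4.39 log2 CPM in WT replicates 10, 11 and 12 and 6.02, 5.03 and 5.46 in HRP2-KO replicates 6, 7 and 44, so replicate 7 lay within the WT range. Col1a1 was the 1 that passed when adjusted over the list alone (adjusted p = 0.0124). None passed over all genes. The list ranked above other genes in limma's camera test (adjusted p = 0.0125), and not with an estimated correlation (adjusted p = 0.445 with an estimated correlation). The call was lost without WT replicate 12 (adjusted p = 0.0519) and with the macrophage level as a covariate, which was added after seeing the data (adjusted p = 0.117).

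Genes of the extracellular matrix and the contractile cytoskeleton were also mostly higher in HRP2-KO. Acta2, the smooth muscle actin gene, was at 4626 ± 847 CPM in HRP2-KO against 1082 ± 163 CPM in WT (SD, n = 3 each), 4.28-fold higher. Cnn1, the actin-binding calponin of smooth muscle, was at 276 ± 8.16 against 32.8 ± 17.4 CPM, and Tagln at 831 ± 200 against 225 ± 81.7 CPM. Col5a2, a fibrillar collagen chain, was at 2887 ± 892 against 914 ± 279 CPM. Of 24 tested members 22 were higher, 6 of them past the threshold when adjusted over the list alone and 0 over all genes. The list as a whole ranked above other genes in camera (adjusted p = 2.0e-04, and adjusted p = 0.445 with an estimated correlation). The list mean was highest in HRP2-KO replicate 7 at 10.1 log2 CPM, and in replicate 44 it lay within the WT range at 8.79.

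Adipocyte genes moved in both directions. Adipoq, the fat-cell hormone adiponectin, was at 8.37 ± 9.23 CPM in WT and 0.0491 ± 0.0488 CPM in HRP2-KO (SD, n = 3 each), with WT values from 1.55 to 18.9 CPM. Fabp4, a fatty-acid carrier, was higher in HRP2-KO at 94.8 ± 59.3 CPM against 19.7 ± 5.59 CPM in WT. Zfp423, a regulator of preadipocytes, was at 4.47 ± 0.645 CPM in WT and 1.97 ± 0.522 CPM in HRP2-KO. Plin4, a lipid-droplet protein, was at 15.4 ± 6.73 CPM in WT and 2.68 ± 2.65 CPM in HRP2-KO. Its annotated span (chromosome 17, 56100587 to 56109948) adjoins the targeted gene and overlaps only the last bases of Hdgfl2, which ends at 56100605. Reads in that short overlap cannot be assigned to 1 gene without strand. Of 19 tested members 14 were lower, and 1 in each direction passed when adjusted over the list alone, with 0 over all genes. In camera the list ranked below other genes (adjusted p = 0.0409, and adjusted p = 0.445 with an estimated correlation), a call lost without any 1 of WT replicates 10 and 11 and HRP2-KO replicates 6 and 44 (adjusted p from 0.0509 to 0.109), with the sex covariate (adjusted p = 0.0711) and with the macrophage covariate (adjusted p = 0.271). The list mean of HRP2-KO replicate 7, at 5.04 log2 CPM, lay within the WT range of 5.03 to 5.65, as its macrophage mean did.

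Among the niche factors by which marrow stroma supports blood formation, Ebf3, a transcription factor of marrow stromal cells, was at 34.7 ± 7.62 CPM in WT and 2.60 ± 0.892 CPM in HRP2-KO (SD, n = 3 each), 13.3-fold lower. Kitl, stem cell factor, was at 125 ± 47.1 against 30.1 ± 14.2 CPM, and Il7, a lymphoid growth factor, at 10.1 ± 1.26 against 3.73 ± 1.0 CPM. Csf1, the macrophage growth factor, was at 2685 ± 586 against 1386 ± 575 CPM. Of 23 tested members 13 were lower, and Ebf3, Kitl and Il7 passed when adjusted over the list alone (adjusted p = 0.000515, 0.0191 and 0.0191), with 0 over all genes. The list as a whole was not called by camera (adjusted p = 0.0876), and was called lower without WT replicate 10 (adjusted p = 0.0342) or HRP2-KO replicate 7 (adjusted p = 0.0442). Chondrocyte genes were not called (adjusted p = 0.863). Col2a1, cartilage collagen, was at 260 CPM in HRP2-KO replicate 6 and at 2.78 to 16.9 CPM elsewhere, and its log2 fold change of 2.66 became -1.52 without that replicate. Matn3, Col11a2 and Hapln1 were at most at 7.25 CPM in any library.

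Targets and regulators of BMP and TGF-beta signalling were mostly lower in HRP2-KO. Id3, a transcriptional target of BMP, was at 269 ± 31.0 CPM in WT and 135 ± 8.18 CPM in HRP2-KO (SD, n = 3 each). Grem1, a secreted BMP antagonist, was at 26.1 ± 12 against 5.63 ± 2.14 CPM, and Bmp6, a ligand, at 9.39 ± 2.84 against 1.18 ± 0.998 CPM. Id4 was at 65.8 ± 22.0 against 24.8 ± 8.89 CPM. Of 27 tested members 22 were lower, and Id3, Grem1 and Bmp6 passed when adjusted over the list alone, with 0 over all genes. Camera ranked the list below other genes (adjusted p = 2.6e-04, and adjusted p = 0.445 with an estimated correlation). The list mean of HRP2-KO replicate 7 was 5.28 log2 CPM, next to the WT range of 5.30 to 5.66, while replicates 6 and 44, which had the lowest macrophage means, were at 4.38 and 4.01.

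Wnt pathway genes were not called as a list (camera adjusted p = 0.233), though single members stood apart. Sfrp4 and Sfrp2 both encode secreted frizzled-related proteins that bind Wnt ligands, and they went opposite ways. Sfrp4 was at 26.2 ± 20.6 CPM in WT and 0.726 ± 0.428 CPM in HRP2-KO, and Sfrp2 at 22.6 ± 10.1 and 160 ± 66.2 CPM (SD, n = 3 each). Wnt4 was at 14.7 ± 11.6 against 1.01 ± 0.204 CPM, and Nkd1, a feedback inhibitor of the pathway, at 8.14 ± 1.07 against 2.25 ± 1.01 CPM. Of 23 tested members 5 passed lower and 1 higher when adjusted over the list alone, and 0 over all genes.

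Cell cycle genes were higher in HRP2-KO in all 26 of the tested members, with a median log2 fold change of 2.46. Cdc20, an activator of the anaphase-promoting complex, was at 45.2 ± 18.7 CPM against 6.85 ± 2.55 CPM in WT (SD, n = 3 each), 6.60-fold higher. The mitotic kinases Aurkb and Plk1 were at 26.7 ± 11.2 against 4.15 ± 1.29 CPM and at 50.7 ± 18.5 against 8.16 ± 3.38 CPM. Mcm4, part of the replicative helicase, was at 52.4 ± 5.78 against 22.7 ± 2.75 CPM. Of the 26 genes 23 passed when adjusted over the list alone and 0 over all genes, and 23 passed over all genes without HRP2-KO replicate 7. This list ranked first in camera, above other genes (adjusted p = 1.1e-14, and adjusted p = 0.445 with an estimated correlation). The list mean was 3.03 to 3.92 log2 CPM in WT and 5.77, 4.95 and 6.15 in HRP2-KO replicates 6, 7 and 44, whose macrophage means were 5.03, 8.82 and 6.04.

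Genes of the p53 response and senescence were not called as a list (adjusted p = 0.863), and camera ranked them downward while their median and mean log2 fold changes were both 0.05. Trp53inp1, a p53-induced stress gene, was at 159 ± 10.8 CPM in WT and 80.1 ± 15.9 CPM in HRP2-KO (SD, n = 3 each). Lmnb1, a nuclear lamina gene that is lost in senescent cells, was at 5.91 ± 1.24 and 33.1 ± 18.9 CPM. Both passed when adjusted over the list alone (adjusted p = 0.0298) and not over all genes. Ccng1 was at 1314 ± 169 against 795 ± 169 CPM, and Btg2 at 332 ± 56.4 against 173 ± 91.1 CPM.

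In the list of the unfolded protein and integrated stress response, the leading members were enzymes of serine, one-carbon and asparagine metabolism, which are targets of the transcription factor ATF4. Psat1, of serine synthesis, was at 237 ± 116 CPM in HRP2-KO against 39.5 ± 10.1 CPM in WT (SD, n = 3 each), 6.01-fold higher. The mitochondrial folate enzymes Mthfd2 and Shmt2 were at 84.9 ± 29.1 against 19.2 ± 3.30 CPM and at 194 ± 58.7 against 54.7 ± 5.98 CPM. Asns, asparagine synthetase, was at 162 ± 65.0 against 45.1 ± 8.72 CPM. Of 20 tested members 16 were higher, 8 of them past the threshold when adjusted over the list alone and 0 over all genes. Camera ranked the list above other genes (adjusted p = 2.6e-04, and adjusted p = 0.445 with an estimated correlation).

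Glycolytic and cholesterol-synthesis genes were also mostly higher in HRP2-KO. The glycolytic enzymes Pfkl and Pgam1 were at 232 ± 47.4 against 99.6 ± 8.72 CPM and at 906 ± 131 against 488 ± 35.3 CPM in WT (SD, n = 3 each). Gapdh was at 5650 ± 1762 against 2233 ± 183 CPM and Eno1 at 1621 ± 379 against 826 ± 23.7 CPM, both families with processed pseudogenes that can share reads, and both highest in HRP2-KO replicate 44. Of 20 hypoxia and glycolysis genes 18 were higher, and these 4 passed when adjusted over the list alone. Camera ranked that list above other genes (adjusted p = 4.2e-04, and adjusted p = 0.445 with an estimated correlation), a call lost without HRP2-KO replicate 7 (adjusted p = 0.0984), whose list mean was 7.94 log2 CPM against 7.02 and 6.88 in replicates 6 and 44. All 19 tested cholesterol-synthesis genes were higher, with a median log2 fold change of 0.82, and 0 passed when adjusted over the list alone. Without HRP2-KO replicate 7, 14 of 20 tested members passed higher over all genes, as did 1694 of all 13983 tested genes. Stard4 was at 22.6 ± 4.92 against 12.9 ± 2.20 CPM, Fdps at 115 ± 104 against 29.0 ± 3.86 CPM and Cyp51 at 102 ± 57.3 against 42.7 ± 9.52 CPM. Camera ranked the cholesterol list above other genes (adjusted p = 5.1e-04, and adjusted p = 0.619 with an estimated correlation), a call lost with the macrophage covariate (adjusted p = 0.197). HRP2-KO replicate 7, at 4.77 log2 CPM, lay within the WT range of 4.70 to 4.94 for this list.

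Immediate early genes, which respond within minutes to serum, growth factors or handling, were mostly lower in HRP2-KO. Fosb was at 657 ± 133 CPM in WT and 91.1 ± 9.75 CPM in HRP2-KO (SD, n = 3 each), 7.21-fold lower, and Fos at 930 ± 44.9 and 195 ± 42.6 CPM. Jun, the AP-1 partner of Fos, was at 592 ± 178 against 172 ± 66.5 CPM. Zfp36, an RNA-binding protein that destabilises inflammatory transcripts, was at 866 ± 52.3 against 161.5 ± 52.1 CPM. Of 18 tested members 14 were lower, and 7 lower and 2 higher passed when adjusted over the list alone, with 0 over all genes. Camera ranked the list below other genes (adjusted p = 4.2e-04, and adjusted p = 0.445 with an estimated correlation).

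Enzymes and readers of histone acetylation and crotonylation, the modifications named in the series title, were not called as a list (camera adjusted p = 0.617). Their mean log2 CPM was 5.14 ± 0.0112 in WT and 5.15 ± 0.108 in HRP2-KO (SD, n = 3 each). Hdac3 was at 78.1 ± 20.9 against 46.9 ± 3.97 CPM and Hdac1 at 107 ± 6.63 against 79.9 ± 5.65 CPM in WT, both deacetylases with decrotonylase activity. Sirt3 was at 6.09 ± 0.423 against 9.38 ± 1.01 CPM, and Acox3, a peroxisomal acyl-CoA oxidase, at 42.0 ± 13.8 against 72.7 ± 10.2 CPM. Of 30 tested members 0 passed when adjusted over the list alone or over all genes, and 7 had an unadjusted p below 0.05, as 21.8% of all tested genes did. Without HRP2-KO replicate 7, 5 members passed higher and 2 lower over all genes. In that fit 3370 of all 13983 tested genes passed. In the list of the HDGF family and H3K36 methylation, Hdgfl2 was the 1 of 18 that passed when adjusted over the list alone. Its relative Hdgf was at 472 ± 152 CPM in HRP2-KO against 282 ± 12.7 CPM in WT, Hdgfl3 at 22.5 ± 8.30 against 42.7 ± 8.60 CPM, and Iws1, a transcription elongation factor, at 43.2 ± 2.84 against 30.4 ± 0.926 CPM. The median of this list was 0.02 and its mean -0.12 on the log2 scale, and camera did not call it (adjusted p = 0.863).

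The macrophage list mean lay below the WT range in HRP2-KO replicates 6 and 44 and within it in replicate 7. Mrc1, the mannose receptor, was at 1366, 643 and 478 CPM in WT replicates 10, 11 and 12, and at 35.0, 257 and 31.0 CPM in HRP2-KO replicates 6, 7 and 44. The complement gene C1qc was at 783 to 2226 CPM in WT, and at 77.2, 860 and 157 CPM in the same 3 HRP2-KO libraries. Cd68, a lysosomal protein, and Fcgr3, an Fc receptor, had WT and HRP2-KO means of 546 ± 237 against 171 ± 184 CPM and 530 ± 275 against 163 ± 189 CPM (SD, n = 3 each). Of 20 tested members 17 were lower, and 0 passed when adjusted over the list alone or over all genes. Without HRP2-KO replicate 7, 17 of the 20 passed over all genes. Camera ranked the list below other genes (adjusted p = 2.0e-04, and adjusted p = 0.619 with an estimated correlation).

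Interferon-response genes were not called (camera adjusted p = 0.747), with 19 of 20 higher in the fit. Isg15 and Ifi44 were at 106 and 134 CPM in HRP2-KO replicate 7 and at most at 13.2 and 8.78 CPM in the other 5 libraries. Usp18 and Gbp2 were at 66.3 and 95.5 CPM in replicate 7 and at most at 5.57 and 23.0 CPM elsewhere. Without that replicate the list was called lower in HRP2-KO (adjusted p = 7.5e-04), and without replicate 6 higher (adjusted p = 0.0433). It was also called higher with the macrophage covariate (adjusted p = 1.3e-09), and its adjusted p was 0.943 with an estimated correlation. The NF-kB and inflammatory secretion list was not called (adjusted p = 0.617, ranked downward with a median of 0.08 and a mean of 0.71 on the log2 scale), and was called lower without replicate 7 (adjusted p = 0.00842). Its members included Cxcl2, a neutrophil-attracting chemokine, at 313 ± 237 CPM in WT and 25.6 ± 32.1 CPM in HRP2-KO, and Ccl5, at 0.490 ± 0.0574 and 4.53 ± 3.30 CPM (SD, n = 3 each). Nfkbia and Tnfaip3, feedback inhibitors of NF-kB, were at 225 ± 27.5 against 72.0 ± 48.1 CPM and at 121 ± 40.8 against 27.0 ± 28.4 CPM.

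Among other cell types that marrow cultures can hold, 3 of the 5 tested neutrophil genes were lower in HRP2-KO and 2 higher. Camera ranked the neutrophil list below other genes (adjusted p = 0.0409, and adjusted p = 0.446 with an estimated correlation). The call was lost without WT replicate 12 or HRP2-KO replicate 6 or 44 (adjusted p from 0.0519 to 0.185) and with the sex or macrophage covariate (adjusted p = 0.0716 and 0.452). These genes were near the detection limit. S100a9 had 17, 12 and 11 counts in the WT libraries and 0 in each HRP2-KO library. Ngp had 52 counts over WT and 2 over HRP2-KO, and Camp had 51 and 23. S100a8 was higher, with 41 counts over WT and 111 over HRP2-KO, 101 of them in replicate 7. The osteoclast list was not called (adjusted p = 0.617). Its member Ctsk, a collagen-degrading protease that stromal cells also express, was at 52.3 ± 5.91 CPM in HRP2-KO against 27.7 ± 1.99 CPM in WT, and Atp6v0d2, a proton-pump subunit, at 1.59 ± 1.48 against 10.7 ± 5.26 CPM (SD, n = 3 each). Both passed when adjusted over the list alone and not over all genes, while Tnfrsf11a and Nfatc1 did not pass either way. The endothelial list was not called (adjusted p = 0.0875), with Flt1 at 16.5 ± 5.28 CPM in WT and 5.40 ± 2.30 CPM in HRP2-KO, and Plvap, Egfl7 and Vwf at most at 4.51 CPM in any library. The endothelial call appeared without WT replicate 10 (adjusted p = 0.0106) or HRP2-KO replicate 44 (adjusted p = 0.0467). The muscle, erythroid and lymphocyte lists had 4, 3 and 1 tested genes and were not tested.

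**Figure D3:**
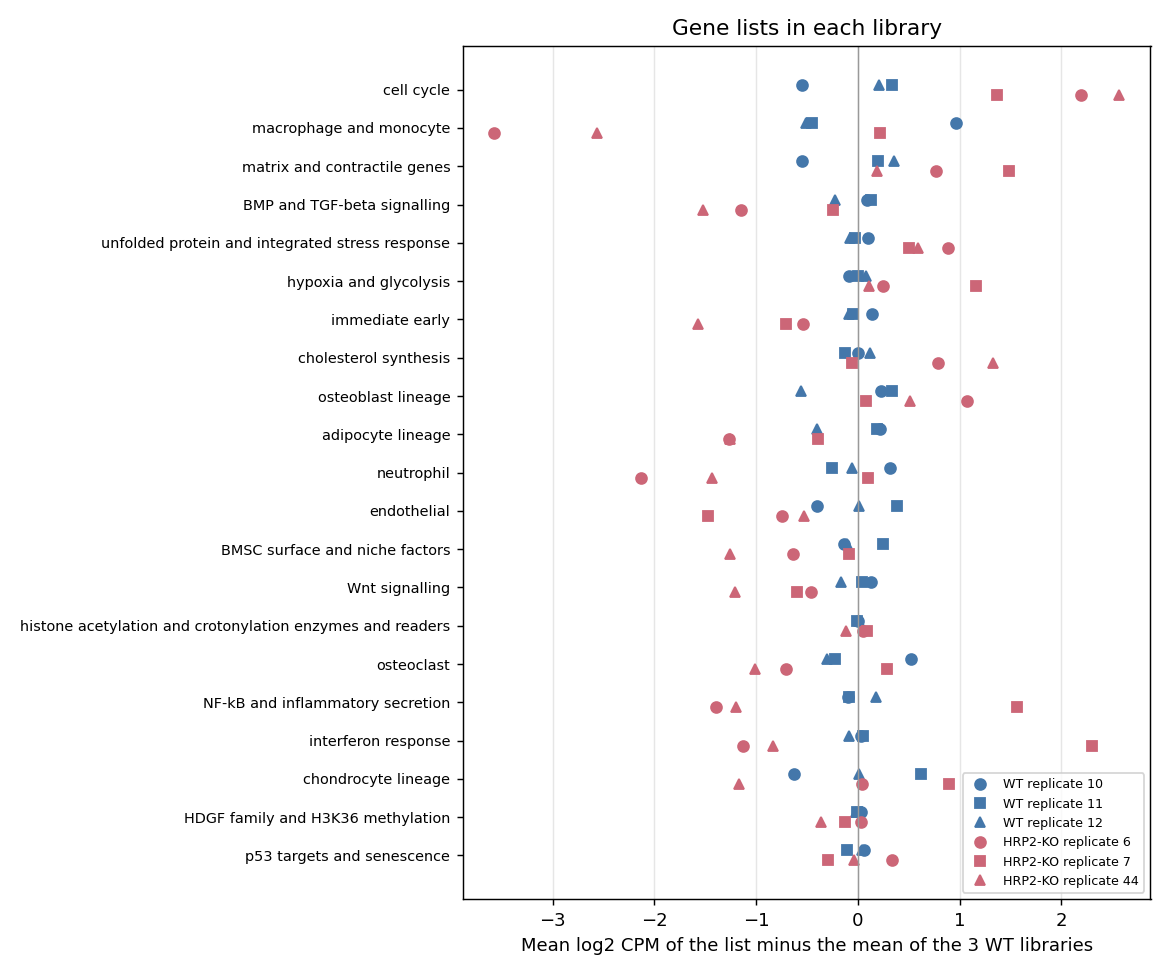
Mean log2 CPM of each of the 21 tested gene lists in each library, minus the mean of the 3 WT libraries (horizontal axis, log2 units), ordered by camera's adjusted p with the smallest at the top. Blue points are WT and red points HRP2-KO libraries, with a circle, square and triangle for replicates 10, 11 and 12 of WT and 6, 7 and 44 of HRP2-KO. All 3 HRP2-KO libraries lie above all 3 WT libraries for the cell cycle list, while HRP2-KO replicate 7 lies apart from replicates 6 and 44 for the macrophage and interferon lists.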

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

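The sex covariate, the macrophage covariate and the robust fit were chosen after the results were seen. No paired analysis was possible because the groups share no replicate numbers in the labels. The count of 1 gene held with RLE and upper-quartile factors, without a filter, with the 1 CPM filter, glmTreat, the minimum fold of 2, the robust fit and the macrophage covariate. It became 1553 with DESeq2 (840 higher, 713 lower, 3431 adjusted p-values not given), 37 with voom (7 and 30), 42 with limma on log2(TPM + 1) (6 and 36), 27 on log2(TPM + 0.1) (2 and 25) and 3 with the sex covariate (0 and 3), and the cause was not tested. Leaving out 1 replicate gave 0 to 3370 genes, with the lowest without HRP2-KO replicate 44 and the highest without HRP2-KO replicate 7, which lowered the biological coefficient of variation from 0.432 to 0.319. The median log2 fold change was -0.21 and -0.24 over the 12665 genes of the TPM fits and 0.02 over the 13696 genes of edgeR, which differ in unit, filter and model at once. Hdgfl2 was lower in every setting run. It also passed the threshold without HRP2-KO replicate 7 (-2.54), with DESeq2 (log2 fold change -2.77), voom (-2.86), TPM + 1 (-2.95) and TPM + 0.1 (-3.13). Its range over left-out replicates was -3.19 to -2.54, with adjusted p from 0.0152 to 0.275. The 11 called lists became 0 with an estimated correlation (smallest adjusted p = 0.445) and 0 with fry (smallest 0.0732), and 9 to 12 with a replicate left out. Without HRP2-KO replicate 7, 12 were called, 9 of them among the 11. The sex covariate gave 9 and the macrophage covariate 8. The endothelial list was called without a filter (adjusted p = 6.2e-04) and with the macrophage covariate (0.0151), which also called the interferon list higher (1.3e-09).

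Directions reversed for 5 named genes when a replicate was left out. Log2 fold changes ranged from -1.42 to 0.16 for Camp, -1.52 to 3.24 for Col2a1, -1.33 to 2.10 for S100a8, -0.48 to 2.69 for Usp18 and -0.025 to 1.59 for Gbp2. S100a8 was -0.15 on log2(TPM + 0.1) and Col2a1 -0.87 with the macrophage covariate. Camera ranked 5 lists the other way when some replicates were left out, none past the threshold except interferon genes without HRP2-KO replicate 7 (adjusted p = 7.5e-04). The others were chondrocyte genes without WT replicate 10 or HRP2-KO replicate 6 or 7 (0.895, 0.833 and 0.641), p53 genes without WT replicate 10 or 12 or HRP2-KO replicate 7 (0.993, 0.982 and 0.360), and, without HRP2-KO replicate 44, the HDGF family (0.492) and NF-kB genes (0.844). Over all 6 replicates left out in turn, those that kept direction included, adjusted p ranged from 0.409 to 0.895 for chondrocyte, 0.492 to 0.993 for the HDGF family, 0.265 to 0.993 for p53, 7.5e-04 to 0.826 for interferon and 0.00842 to 0.867 for NF-kB genes. Ranks also turned in other settings. Without a filter the adjusted p was 0.736 for chondrocyte, 0.891 for the HDGF family and 0.885 for p53, and with the 1 CPM filter 0.834 for chondrocyte genes. It was 0.917 for interferon with the sex covariate, and 0.737 for osteoclast and 0.146 for NF-kB genes with the macrophage covariate. The cause was not tested for these. Among named genes, 487 of the comparisons with a replicate left out and 1008 of the others kept direction and side of the threshold, and 70 and 103 newly passed it. At this dispersion the simulated test recovered 4% of 2-fold changes, so smaller differences were mostly not detectable.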

Other observations

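The genes in the first 2 paragraphs were chosen after their values were seen. Several genes outside the fixed lists had group means far apart without passing edgeR's threshold over all genes. Lpin1, a phosphatidate phosphatase, was at 83.2 ± 2.12 CPM in WT and 30.8 ± 0.324 CPM in HRP2-KO (SD, n = 3 each, adjusted p = 0.0575). Znhit6, a factor in small nucleolar ribonucleoprotein assembly, was at 205 ± 7.0 against 50.3 ± 7.13 CPM, and Arrdc3, an arrestin-domain protein, at 42.9 ± 2.35 against 9.67 ± 1.56 CPM (adjusted p = 0.0575 each). Folh1, a glutamate carboxypeptidase, was 155-fold lower in HRP2-KO and the guidance factor Sema3c 26.0-fold lower (adjusted p = 0.0711 each). The matrix protein gene Efemp1 was at 599 ± 147 against 48.1 ± 45.6 CPM. In the other direction, Tnn, tenascin-N, was at 488 ± 350 CPM in HRP2-KO against 25.6 ± 21.3 CPM. Bcat1, of branched-chain amino acid metabolism, was at 91.9 ± 27.4 against 9.62 ± 2.04 CPM, and Mthfd1l, a mitochondrial folate enzyme, at 63.8 ± 9.91 against 11.7 ± 2.78 CPM.

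Ribosomal protein genes were higher in HRP2-KO in 81 of 81 cases, with a median log2 fold change of 1.23. All 81 were higher with RLE and upper-quartile factors and on log2(TPM + 1), and 80 on log2(TPM + 0.1), where the median was 0.82, and the median was 0.90 after the length trend was removed. None passed the edgeR threshold, 67 had an unadjusted p below 0.05, and 72 passed higher without HRP2-KO replicate 7. Their mean log2 CPM was 7.75 to 8.25 in WT and 8.99, 8.27 and 9.87 in HRP2-KO replicates 6, 7 and 44. These genes have short transcripts and many pseudogenes, and HRP2-KO replicate 44 had the highest level of short transcripts as a class.

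Of the tests that follow, those on genotype, a mislabelled sample, the macrophage content of replicate 7 and a lower macrophage share were chosen after the result was seen. The number of genes past the threshold in the real grouping was 1, and the highest of the other 9 of the 10 splits was 0, with 1 split of 10 reaching the real count. For gene lists the real count was 11 and the highest other also 11, so 2 of 10 splits reached it. That other split set WT replicate 10 with HRP2-KO replicates 6 and 44. Each of the other 9 splits called at least 4 lists, so list calls at the preset correlation also arose when the genotypes were mixed. The 10 splits are too few for a share under 0.05.

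A set of 15 gut epithelial genes, picked because they differed, had 3469 counts in WT and 32 in HRP2-KO. Of these, Ces2e alone gave 1625 and 24. Lypd8 had 134, 189 and 126 counts in WT replicates 10, 11 and 12 and 0 in each HRP2-KO library, and Dmbt1 had 58, 109 and 80 against 0. RNA or reads from colon epithelium may be a source. Of 24 further colon genes, 66.7% (16 of 24) were higher in every WT library than in every HRP2-KO library. The colon gene Cdh17 had more counts in HRP2-KO, 92 against 49 in WT. Chance gives 5% on average over all groupings, but 1919 of all 13696 tested genes also lay higher in every WT library, which is more than that. Of 16 small intestine genes 12.5% did, so that list gave no sign of small intestine. Several of its members had almost no counts, such as Apoc3 with 0 in any library and Sis and Alpi with 3 over WT and 0 over HRP2-KO. Genes this low could hardly meet the criterion, so small intestine is not excluded. The 24 colon genes, 5 of which had counts in every HRP2-KO library, summed to 1039 counts in WT and 256 in HRP2-KO, with Krt20 and Muc2 at 230 and 222 WT counts, but Tff3 and Phgr1, abundant in colon, had 12 and 11, and Muc2 also had 53 counts in HRP2-KO replicate 7. An effect of genotype cannot be told apart from such a source, because the summed colon counts of the WT libraries were within a ratio of 1.48 of each other and the labels name no batch that holds both genotypes.

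HRP2-KO replicate 7 stood apart from replicates 6 and 44. A mislabelled WT sample is argued against by its Hdgfl2 level, at 10.8% of the lowest WT library. Its macrophage genes were 2.78 above the higher of the other HRP2-KO libraries in mean log2 CPM, consistent with a larger macrophage content. That content alone would not account for its interferon genes, which were 2.24 above the highest WT library although its macrophage level lay in the WT range. An interferon response in that culture may be a separate difference, and what set it off was not tested.

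The higher level of cell cycle genes was set against technical explanations. A lower macrophage share, which would raise stromal genes alike, is argued against as the whole cause by the BMSC list, if taken as a stromal reference. Its median was -0.33 on the log2 scale (SD of members 1.25) against 2.46 for cell cycle genes. That list is not a fixed reference, since its members moved both ways, 13 lower and 10 higher. In HRP2-KO replicate 7 the macrophage mean of 8.82 log2 CPM lay within the WT range of 8.09 to 9.56. The cell cycle mean of that library, 4.95, was still above the highest WT library at 3.92. Stromal lists differed, with a median of 1.13 for matrix and contractile genes, so a part from macrophage share stays open. A bias by transcript length is argued against as the whole cause, since the cell cycle median was 2.59 after the length trend was removed. Genotype, batch, culture density, passage and time in culture stay open and were not tested, and proliferation itself was not measured in the data used here.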
